A study of Mus musculus with 15 samples.

How the data were processed

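RNA of 3134 and AtT-20 mouse cells at 0, 2, 4 and 8 h of 100 nM dexamethasone was measured on 15 Affymetrix mouse exon arrays, 1 colour each. The groups were taken from the sample titles, which give line, time and a serial number. The labels describe the 0 h samples both as untreated and as vehicle treated, and they do not say that replicates were separate cultures, so p-values measure only the spread between these arrays, which may be technical. Replicate numbers 1 and 2 were given by the order of the serial numbers, which fall into a lower and a higher run in each line.

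The deposited values are on a log2 scale, 1 per exon probeset and array, and were made with Affymetrix Expression Console and RMA per the submitters' processing notes. Versions and settings are not given in the sources used here. They covered 228090 probesets. The platform annotation gave 1 gene symbol for 207232 of them, several for 3882 and none for 16976, and only the first kind was used. Of 16207 symbols, 14055 were current among the RefSeq genes given (assembly GRCm38.p6, used for names only), 2086 were updated through synonyms and 66 were kept as given. Exon coordinates were not used here. Some listed genes, such as Zbtb16, Klf9 and Gapdh, had no value under their name and were not analysed here.

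The deposited columns were not on a common level. Their medians ran from 7.83 to 8.14 in the first run and from 6.76 to 7.20 in the second run of 3134, and from 7.51 to 7.86 and from 6.93 to 7.22 in AtT-20. Normalized values had been assumed when the tests were fixed, so quantile normalization over the 15 arrays was added after the columns were seen, with the deposited scale and median-centred arrays as alternatives. The highest correlation between 2 arrays, across probesets, was 0.985, and no array was taken for a repeat of another.

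The value of a gene was the median over its probesets, for the 15041 genes with at least 3 probesets (median 13 per tested gene). A gene was tested if the highest of the 8 group means reached the 40th percentile of all values, log2 6.59, which left 9927 genes. Group means were fitted with limma 3.58.1 (lmFit and eBayes, 2-sided moderated test) in R 4.3.3 with data.table (version 1.17.8), on all 15 arrays with 1 spread per gene and 7 residual degrees of freedom. P-values were adjusted by Benjamini and Hochberg's method, with a threshold of 0.05, and every adjusted p of a gene is from limma. The contrasts were each time against 0 h in each line, the mean of the 3 times against 0 h, the difference of the mean responses, 8 h against 2 h in 3134, 4 h against 2 h in AtT-20, and the lines at 0 h. Comparisons within a line share their 0 h arrays, so overlaps between times were not computed as evidence. Calls shared by the lines were set against the number expected for independent lists with a 2-sided Fisher's exact test.

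Unequal change among exons was tested with limma's diffSplice (Simes test per gene) on 144410 probesets of 11438 genes. Gene lists were tested with limma's camera at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the 20 lists with tested members. The lists were glucocorticoid-induced genes, cytokines with chemokines and NF-kB targets, immediate early genes, circadian clock genes, MAP kinase and G protein feedback regulators, the receptor with chaperones and cofactors, corticotroph and pituitary lineage genes, secretory granule genes, markers of other pituitary cell types, epithelial, mesenchymal, immune and endothelial markers, matrix remodelling with TGF-beta targets, cell cycle, cholesterol biosynthesis, lipid and adipogenic genes, heat shock and unfolded protein genes, transporters, apoptosis regulators and housekeeping genes. Some genes stand on more than 1 list.

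The groups, the tests, the lists, the alternatives not named as added, and the rule for named genes were chosen before the data were examined. The rule took, for each time against 0 h, the 5 genes with the largest change each way among those that passed and whose treated arrays all lay on the same side of all control arrays. It took the 5 largest each way for the difference of responses and the comparisons between times, the 8 largest each way between the lines at 0 h, the 3 genes with the smallest adjusted p per line in the exon test, up to 4 members of each list with the smallest p, and always Nr3c1, Fkbp5, Per1, Tsc22d3 and Pomc. Predicted loci could stay unnamed.

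Whether the runs pair the arrays was checked by correlating, across genes, the deviations of arrays from their group means. The correlations were 0.492 to 0.59 over 9 pairs of the same run and line and 0.277 to 0.391 over 12 pairs of the same run number in different lines, so the runs were taken as paired. Fits with the run as a block (5 residual degrees of freedom) are given where they change a call or a count by over 1.5 times.

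The tests were tried on simulated data with known answers, with 50 changed genes per fold size among 9927. For the mean response of 3134, the fit recovered 14% of genes changed by log2 0.5, 56% of those changed by 1 and 92% of those changed by 2, with 3 false calls, and for that of AtT-20 10%, 56% and 92%, with 9 false calls. With a simulated run effect, the recovery at log2 1 for the mean response of 3134 was 60% without and 88% with the block (1 and 9 false calls), and for AtT-20 50% and 90% (0 and 6 false calls). For AtT-20 at 8 h alone 36% were recovered at log2 1. A shifted list was recovered by camera with adjusted p = 1.02e-47 (2.02e-05 with an estimated correlation), and 0 of 19 unchanged lists passed. These lists were random genes with noise drawn separately for each gene. They therefore cannot show false calls at the preset correlation for lists whose members vary together, such as the clock genes (estimated correlation 0.161). For the exon test on 11438 genes with 100 changed by log2 2 and equal spread among the probesets of a gene, diffSplice recovered 76 for 3134 and 72 for AtT-20 with 1 false call each. When each probeset kept its own spread, as estimated from these arrays, it recovered 79 and 81 with 349 and 393 false calls. A test with an own spread per probeset (probeset minus gene median on each array, limma, Simes) was therefore added, which recovered 48 and 39 with 4 and 3 false calls.

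The alternatives were the mean over probesets, no filter on dim genes, dim probesets dropped first, at least 1 probeset per gene, quantile normalization within each line, each line fitted alone, eBayes with trend and robust, the run as a block, and each array left out in turn. For the exon test they were no filter on dim probesets, the run as a block and arrays left out, and for the overlap a threshold of 0.01. Added after the data were seen were the deposited scale and centred arrays, both also with the block, the mean of 2 and 4 h only, a 0 h filter on probesets and the own-spread exon test.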

Results

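Transcript levels were measured on mouse exon arrays in cells of 2 mouse lines before and after exposure to dexamethasone, a synthetic glucocorticoid that binds the glucocorticoid receptor. The 3134 line is a mammary adenocarcinoma line that derives from C127 cells by transformation, and AtT-20 is a corticotroph line of the anterior pituitary, the cell type that makes the hormone precursor Pomc. Cells received 100 nM dexamethasone for 2, 4 or 8 h, and 0 h arrays served as the control of each line. No array held cells kept for 2, 4 or 8 h without dexamethasone. Effects of the hormone therefore cannot be told apart from those of time in culture. A response here means a change against 0 h. Each of the 8 groups of line and time had 2 arrays except AtT-20 at 8 h, which had 1, so 15 arrays were analysed. The number of arrays limits the precision: the median standard error of a log2 fold change between groups of 2 arrays was 0.215, and it was 0.264 for AtT-20 at 8 h. Of 15041 genes with a value, 9927 were bright enough to be tested. The arrays of each line came in a pair of runs, told apart by the serial numbers in the sample titles. Replicate 1 of every group belonged to the first run and replicate 2 to the second. The single AtT-20 array at 8 h was of the first run, while the 0 h mean held both runs. Without the run as a block, comparisons that use this array therefore carry part of any difference between the runs. These are AtT-20 at 8 h, its mean response and the difference between the responses of the lines.

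The first question was which transcripts changed over the time of exposure in 3134 cells. The acute phase glycoproteins Orm1 and Orm2, the iron-siderophore binding protein Lcn2, the metal binding protein Mt2 and Pdk4, a kinase that inhibits pyruvate dehydrogenase, had the largest measured rises at 2 h. Orm1 rose 12.7-fold at 2 h (log2 fold change 3.67 ± 0.374, SE, adjusted p = 0.000295) and by log2 4.25 ± 0.374 at 8 h (adjusted p = 7.73e-05). Its log2 level went from 6.43 ± 0.4 (SD, n = 2) at 0 h to 10.68 ± 0.313 (SD, n = 2) at 8 h. The chemokine Ccl2, which attracts monocytes, had the largest measured fall, with a log2 fold change of -3.39 ± 0.579 at 2 h (adjusted p = 0.014), -3.98 ± 0.579 at 4 h (adjusted p = 0.00323) and -3.07 ± 0.579 at 8 h (adjusted p = 0.0173). Its log2 level was 8.49 ± 0.494 (SD, n = 2) at 0 h and 4.51 ± 0.402 (SD, n = 2) at 4 h. A gene needed a log2 level of 6.59 in some group to be tested. Orm1, Pdk4, Slc10a6 and Fabp4 started below this level in 3134 cells, and Ccl2, Cxcl3, Cxcl5, Pparg, Plau, Nr1d1 and Slc7a11 ended below it at 1 or more times, so the sizes of their changes are limited by background and their ranks are not resolved.

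At 2 h, 93 genes were higher and 28 lower than at 0 h in 3134 cells. Besides Orm1, the largest rises were those of Mt2 (3.58 ± 0.608), Lcn2 (3.29 ± 0.273), Orm2 (3.28 ± 0.304) and Pdk4 (3.12 ± 0.178). Besides Ccl2, the largest falls were those of the neutrophil chemokine Cxcl5 (-2.71 ± 0.29), Ankrd1 (-2.02 ± 0.326), Phlda1 (-1.97 ± 0.299) and the urokinase gene Plau (-1.90 ± 0.194). At 4 h, 134 genes were higher and 56 lower. Mt2 (3.94), Lcn2 (3.91), Orm1 (3.91), Pdk4 (3.46) and Orm2 (3.27) led the rises. After Ccl2, the falls were led by the chemokines Cxcl3 (-2.91 ± 0.632) and Cxcl5 (-2.76), the immune receptor gene Cd300lb (-2.00 ± 0.293) and Pparg (-1.90 ± 0.21), a nuclear receptor of fat cell differentiation. At 8 h, 163 genes were higher and 54 lower. Lcn2 had risen by 4.29 ± 0.273, Pdk4 by 4.10 ± 0.178, Mt2 by 3.96 and Slc10a6, a carrier of sulfated steroids, by 3.63 ± 0.242. The log2 fold change was -2.40 for Cxcl5, -1.99 ± 0.241 for the clock repressor Nr1d1, -1.66 for Cd300lb and -1.65 ± 0.238 for Slc7a11, the cystine and glutamate exchanger. Genes were named here as leading a rise or a fall only if every treated array lay on the same side of both 0 h arrays. Fits with the run as a block called 296 (193 higher and 103 lower), 513 (325 and 188) and 782 (427 and 355) genes, among them all those called without it. Without 1 of the 4 arrays compared, the count at 2 h was 38 (2 h replicate 1), 49 (2 h replicate 2), 39 (0 h replicate 1) or 44 (0 h replicate 2). At 4 h it was 79 (4 h replicate 1), 96 (4 h replicate 2), 71 (0 h replicate 1) or 82 (0 h replicate 2), and at 8 h it was 92 (8 h replicate 1), 107 (8 h replicate 2), 77 (0 h replicate 1) or 75 (0 h replicate 2). The share of higher genes depended on the scaling. On the deposited scale with the run as a block, the median of all genes moved by -0.072, -0.317 and -0.377, and the splits were 119 higher and 59 lower at 2 h, 131 and 335 at 4 h, and 125 and 1029 at 8 h. Without the block, that scale gave 12, 9 and 12 genes. With each array centred on its median and the block, the 8 h split was 477 and 460.

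**Figure D1:**
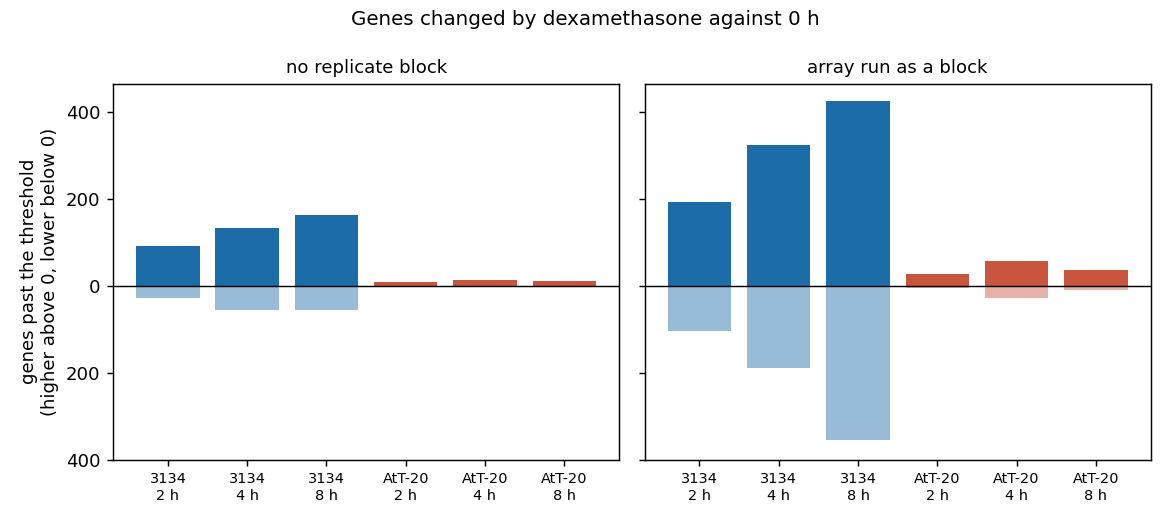
Number of genes that passed the threshold (vertical axis) higher (above 0) or lower (below 0, pale) than at 0 h after 2, 4 and 8 h of dexamethasone (horizontal axis) in 3134 (blue) and AtT-20 (red), without a block on the left and with the array run as a block on the right. At 8 h, 163 genes were higher and 54 lower in 3134 against 11 and 1 in AtT-20 without the block, and 427 and 355 against 36 and 8 with it.

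Over the mean of the 3 times, 178 genes were higher and 63 lower in 3134 cells. Among the 20 lists tested, the genes already known to be induced by glucocorticoids had the largest median rise. Of the 32 tested genes of that list, 21 rose and 0 fell by limma (24 and 1 with the run as a block, and 22 and 1 when adjusted over the list alone). The median log2 fold change was 1.47 (adjusted p = 7.17e-48; adjusted p = 0.000824 with an estimated correlation). Pdk4 rose by 3.56 ± 0.146, the receptor's co-chaperone gene Fkbp5 by 2.84 ± 0.126 and the glutamine synthetase gene Glul by 2.44 ± 0.121. The clock gene Per1 rose by 2.49 ± 0.144 and the leucine zipper gene Tsc22d3, which encodes an anti-inflammatory protein, by 2.73 ± 0.27. Fkbp5 was at 2.66, 3.05 and 2.81 at 2, 4 and 8 h (± 0.154 each), Per1 at 2.69, 2.57 and 2.22 (± 0.177), and Tsc22d3 at 2.50, 2.67 and 3.02 (± 0.33). Nr3c1, the gene of the receptor itself, fell by 0.69 ± 0.137 over the mean (adjusted p = 0.0181). Its log2 fold change passed at 4 h (-0.99 ± 0.168, adjusted p = 0.0083) but not at 2 h (-0.66, adjusted p = 0.117; 0.0191 with the block) or 8 h (-0.43, adjusted p = 0.317). Pomc, whose transcript lay at 5.20 ± 0.014 (log2, SD, n = 2) in 3134 cells at 0 h, below the level needed for testing, had log2 fold changes of -0.43, -0.40 and -0.17 and passed at none of the 3 times.

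**Figure D2:**
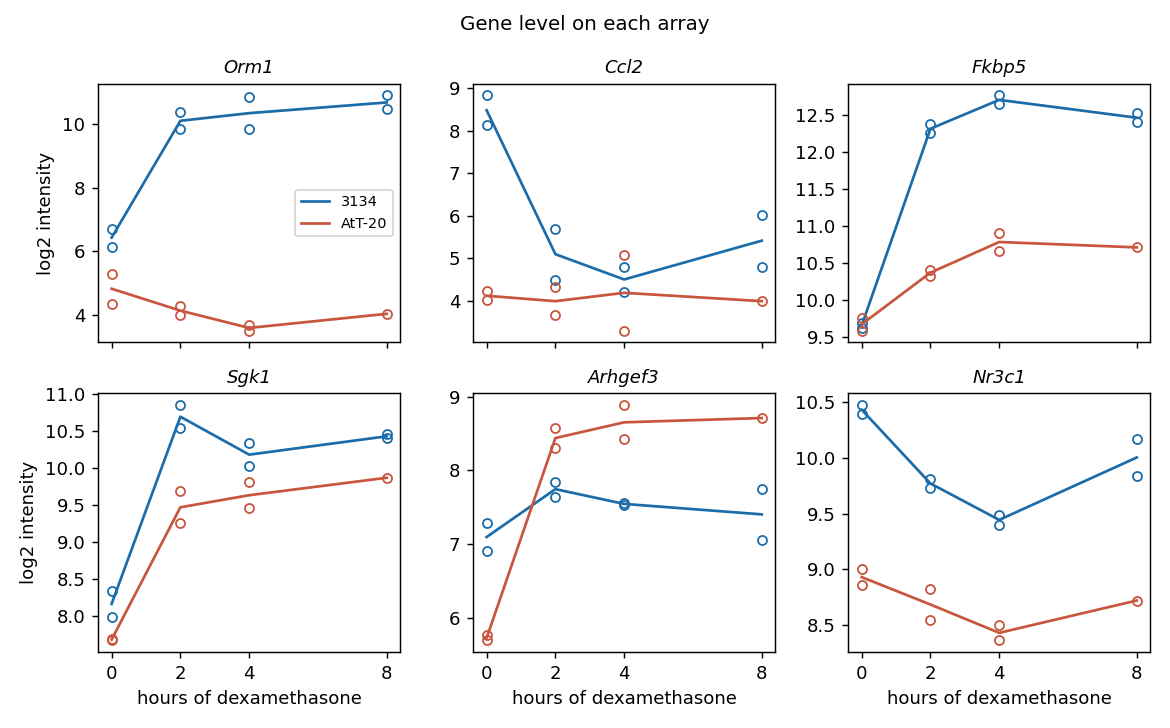
Log2 intensity (vertical axis) of Orm1, Ccl2, Fkbp5, Sgk1, Arhgef3 and Nr3c1 at 0, 2, 4 and 8 h of dexamethasone (horizontal axis) in 3134 (blue) and AtT-20 (red), with circles for single arrays and lines through the group means. Fkbp5 started at 9.65 in 3134 and 9.67 in AtT-20 and stood at 12.46 and 10.71 at 8 h, while Arhgef3 rose in AtT-20 from 5.73 to 8.71.

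Some chemokine and matrix genes fell in 3134 cells. Of 15 tested cytokines, chemokines and NF-kB targets, 6 fell and 0 rose by limma (10 and 0 with the run as a block, 9 and 0 when adjusted over the list alone). The median was -0.63 (adjusted p = 1.55e-08; adjusted p = 0.00349 with an estimated correlation). The genes that fell included Ccl2 (-3.48 ± 0.473), Cxcl5 (-2.62 ± 0.237), Cxcl1 (-1.03 ± 0.18) and Ccl7 (-0.75 ± 0.146). Of 20 genes of extracellular matrix remodelling and TGF-beta targets, 4 fell and 0 rose (7 and 0 with the block, 6 and 0 adjusted over the list alone). The median was -0.23 (adjusted p = 1.67e-06; adjusted p = 0.00528 with an estimated correlation). The 4 genes were Plau (-1.55 ± 0.158), the matrix glycoprotein gene Thbs1 (-0.82 ± 0.153), the TGF-beta inhibitor Smad7 (-0.62 ± 0.121) and the urokinase receptor gene Plaur (-0.86 ± 0.179). Immediate early genes are transcribed within minutes of a stimulus. Of the 24 tested, 2 fell, Ier3 (-1.27 ± 0.158) and Klf4 (-0.96 ± 0.165), and 0 rose (8 and 3 with the block, 8 and 1 adjusted over the list alone). Fosl2 (-1.13, adjusted p = 0.0637; 0.000101 with the block) and Klf10 (-0.55, adjusted p = 0.0922; 0.0235 with the block) passed only with the block. The list passed with a median of -0.26 (adjusted p = 0.00148) but had an adjusted p = 0.203 with an estimated correlation. Among 15 circadian clock genes, Per1, Nfil3 (2.29 ± 0.155), Per2 (1.00 ± 0.145) and Bhlhe41 (0.64 ± 0.12) rose, so 4 rose, and 1 fell, Nr1d1 (-0.94), which was named here after its values were seen. Adjusted over the list alone, 5 rose and 1 fell. The median was 0.30 (adjusted p = 0.00238 by camera, and adjusted p = 0.203 with an estimated correlation). Per1, Per2 and Cry2 are also on the list of induced genes.

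Of 34 cell cycle genes, limma called 0 higher and 0 lower (0 and 3 with the block, 0 and 0 when adjusted over the list alone). The list as a whole lay lower, with a median of -0.17 (adjusted p = 0.00658; adjusted p = 0.247 with an estimated correlation). The replication licensing gene Cdc6 was at -0.73 (adjusted p = 0.38; 0.0323 with the block) and Cdt1 at -0.40 (0.0465 with the block). Of 21 cholesterol biosynthesis genes, 0 were called either way (0 and 1 with the block, 0 and 0 when adjusted over the list alone). The median was -0.13 (adjusted p = 0.0342; adjusted p = 0.203 with an estimated correlation), with Insig1 at -0.63 (adjusted p = 0.118; 0.00407 with the block) and Sc5d at -0.43. Over all 9927 genes, 900 had an unadjusted p under 0.05 in this comparison.

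The other lists did not pass as lists in 3134 cells, though some of their members changed. Among 23 MAP kinase and G protein feedback regulators (adjusted p = 0.306), 4 rose and 2 fell (6 and 4 with the block, 4 and 4 adjusted over the list alone). They included the phosphatase gene Dusp1 (2.78 ± 0.171), the G protein regulator Rgs2 (2.41 ± 0.222), the receptor kinase inhibitor Errfi1 (1.95 ± 0.289) and Dusp4 (-1.22 ± 0.201). Among 20 lipid and adipogenic genes (adjusted p = 0.199), 4 rose and 1 fell (4 and 2 with the block and also when adjusted over the list alone). The fatty acid binding protein gene Fabp4 (1.88 ± 0.202) and the lipid droplet gene Plin4 (1.38 ± 0.159) rose with Pdk4, and Pparg fell (-1.62 ± 0.171). Among 19 apoptosis regulators (adjusted p = 0.106), 3 rose and 0 fell (4 and 3 with the block, 4 and 1 adjusted over the list alone). These were Gadd45g (1.37 ± 0.174), Trp53inp1 (1.19 ± 0.152) and Bcl2l1 (1.67 ± 0.218), whose main product opposes apoptosis. The test of these 3 lists pointed up and so did their means (0.23, 0.24 and 0.15), while their medians were -0.01, -0.04 and -0.02. Among 19 heat shock and unfolded protein genes (adjusted p = 0.191), Chac1 (-1.18 ± 0.16) and Ddit3 (-0.92 ± 0.18) fell and Herpud1 (1.04 ± 0.194) rose (2 higher and 4 lower with the block, 2 and 2 adjusted over the list alone). Hspb1 was at 0.70 and passed only with the block (adjusted p = 0.0234). Among 16 amino acid and ion transporters (adjusted p = 0.0693), Slc7a1 (-0.60) and Slc6a9 (-0.53) fell (0 and 3 with the block, 0 and 2 adjusted over the list alone). Of 18 genes of the receptor, its chaperones and its cofactors (adjusted p = 0.735), Fkbp5 rose and Nr3c1 fell (1 and 1 adjusted over the list alone). The test and the median (-0.07) pointed down and the mean (0.07) up.

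Few markers of cell types passed in 3134 cells. Scg2 was called higher (0.74) among 23 secretory granule genes (adjusted p = 0.0693; 2 and 0 with the block, 1 and 0 adjusted over the list alone), and Pdgfrb (-0.71) fell among 16 mesenchymal genes (adjusted p = 0.341; 0 and 1 adjusted over the list alone). Scg2 lay below the log2 level of 6.59 at all times in 3134, so its rise is not resolved from background. By limma, 0 of 10 corticotroph genes (adjusted p = 0.193), 0 of 8 epithelial (adjusted p = 0.342), 0 of 2 immune (adjusted p = 0.689), 0 of 3 endothelial (adjusted p = 0.851) and 0 of 13 housekeeping genes (adjusted p = 0.809) were called, and 0 when adjusted over each list alone. The block added 1 corticotroph gene. At 0 h in 3134, 10 of the 10 corticotroph, 6 of the 8 epithelial and 16 of the 23 secretory granule genes lay below the log2 level of 6.59. A fall of these genes could not be seen. Of 12 markers of other pituitary cell types, 11 were on the array and 0 were bright enough to be tested. The directions of the 7 lists that passed held with centred arrays. On the deposited scale, where the median of all genes fell by 0.259 with the run as a block, the 2 lists that rose still did, while the 5 that fell were moved further the same way, which is no test of their direction. There the split of called genes was 156 higher and 381 lower, and with quantile normalized values and the block it was 400 and 250. Without 0 h replicate 1 the count over the mean of the 3 times was 109 and without 0 h replicate 2 it was 93.

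In AtT-20 cells, few genes changed at each time of the same exposure. Arhgef3 rose by 2.71 ± 0.243 at 2 h (adjusted p = 0.00056), 2.92 at 4 h (adjusted p = 0.00032) and 2.98 ± 0.298 at 8 h (adjusted p = 0.00226). Its log2 level went from 5.73 ± 0.048 (SD, n = 2) at 0 h to 8.71 on the single array at 8 h. Mdm1, which encodes a microtubule binding protein of centrioles, rose by 2.03 ± 0.179, 2.78 and 2.46 ± 0.22. The kinase gene Sgk1 rose by 1.79 ± 0.21 at 2 h and 1.95 at 4 h. Thbs1 fell by 1.79 ± 0.188 at 4 h (adjusted p = 0.00167) and by 2.13 ± 0.23 at 8 h (adjusted p = 0.00259).

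At 2 h, 9 genes were higher and 0 lower in AtT-20 cells by limma (28 and 4 with the run as a block), and 238 genes had an unadjusted p under 0.05. After Arhgef3, Mdm1 and Sgk1, the largest rises were those of the stress-induced gene Sesn1 (1.75 ± 0.159) and the deubiquitinase gene Usp2 (1.37 ± 0.165). At 4 h, 15 were higher and 2 lower. Cables1 (2.13 ± 0.347) and the protocadherin gene Pcdh17 (1.94 ± 0.206) were among the largest rises, and Spats2l (-1.13 ± 0.164) fell with Thbs1. At 8 h there was 1 treated array, of the first run, set against 0 h arrays of both runs. It was assumed to vary like the other groups. On that array, without a replicate, the quinone reductase gene Nqo1 (2.79 ± 0.295) and the chemokine Ccl3 (2.31 ± 0.378) were higher. So was the tyrosine aminotransferase gene Tat (2.36 ± 0.34), a liver enzyme induced by glucocorticoids. Ccl3 reached the level needed for testing, log2 6.59, in that group alone. Per1 rose at all 3 times, by 1.32 (adjusted p = 0.0137), 1.17 (adjusted p = 0.0219) and 1.495 (adjusted p = 0.0188). Fkbp5 passed at 4 h (1.11, adjusted p = 0.015) but not at 2 h (0.70, adjusted p = 0.323) or 8 h (1.04, adjusted p = 0.0931; 0.0222 with the block). Tsc22d3 was at 0.77, 0.56 and 0.90, Nr3c1 at -0.25, -0.50 and -0.21 and Pomc at 0.08, 0.04 and 0.12, and none of these passed. Blocking by run gave 32, 86 (58 higher and 28 lower) and 44 (36 and 8) genes at 2, 4 and 8 h. Without 1 array, the count at 2 h was 3 (2 h replicate 1), 5 (2 h replicate 2), 3 (0 h replicate 1) or 3 (0 h replicate 2). At 4 h it was 9 (4 h replicate 1), 11 (4 h replicate 2), 9 (0 h replicate 1) or 7 (0 h replicate 2), and at 8 h it was 7 without 0 h replicate 1 or 0 h replicate 2. On the deposited scale with the block, the median of all genes moved by 0.012, -0.216 and 0.148, and the splits were 26 higher and 2 lower, 20 and 11, and 35 and 2. Without the block that scale gave 0 genes at each time by limma.

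Over the mean of the 3 times, 19 genes rose and 1 fell in AtT-20 cells, and 347 had an unadjusted p under 0.05. Arhgef3 (2.87 ± 0.207), Mdm1 (2.42 ± 0.152), Sgk1 (1.98 ± 0.179), Nqo1 (1.85 ± 0.204), Tat (1.76 ± 0.236) and Sesn1 (1.74 ± 0.135) rose. So did Per1 (1.33 ± 0.15), Ddit4 (1.14 ± 0.154), an inhibitor of mTOR signalling, Usp2 (1.14 ± 0.14) and Fkbp5 (0.95 ± 0.131), and Thbs1 fell by 1.69 ± 0.16. Pomc was unresolved, at 0.08 ± 0.312 with a 95% confidence interval from -0.603 to 0.762 (adjusted p = 0.999). In AtT-20, 4 of its 5 probesets lay above the 99th percentile of all values in the 0 h arrays. Of the 32 glucocorticoid-induced genes, 5 rose (Sgk1, Sesn1, Per1, Ddit4 and Fkbp5) and 0 fell by limma (10 and 0 with the block, 10 and 1 when adjusted over the list alone). The median was 0.49, and 0.35 with the block (adjusted p = 8.04e-19 without the block by camera, and adjusted p = 0.016 with an estimated correlation). Tsc22d3 (0.74, adjusted p = 0.999), Rasd1 (1.66, adjusted p = 0.0835), Bcl6 (0.98, adjusted p = 0.0673) and Rgs2 (1.00, adjusted p = 0.233) did not pass. With the block, Rasd1 (adjusted p = 1.18e-05) and Rgs2 (adjusted p = 0.00128) did. Of 15 circadian clock genes, 1 rose, Per1 (3 and 0 with the block and also when adjusted over the list alone), with a median of 0.12 (adjusted p = 0.000414; adjusted p = 0.229 with an estimated correlation). Per2 was at 0.67 (adjusted p = 0.222 by limma, and 0.025 with the block) and Cry2 at 0.78 (adjusted p = 0.423, and 0.023 with the block). Per1, Per2 and Cry2 are also on the list of induced genes, so the clock list is not a separate result. The other 18 lists did not pass, with adjusted p from 0.1 for apoptosis regulators to 0.894 for housekeeping genes. Among their members only Thbs1, of the matrix list, and Fkbp5, of the receptor list, passed over all genes. The block added calls among feedback regulators (3 and 1), apoptosis (2 and 0), lipid (1 and 1) and endothelial genes (1 and 0). With the block 68 genes rose and 18 fell (44 and 4 on the deposited scale), and the direction of both lists held under each scaling. Without 0 h replicate 2 the count of genes was 6, and without 0 h replicate 1 the number of lists that passed was 5.

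Whether the lines responded differently was tested as the difference of their mean responses. Orm1 differed by 4.85 ± 0.44 in favour of 3134 (adjusted p = 0.000337) and Pdk4 by 4.00 ± 0.21 (adjusted p = 3.8e-06). Lcn2 differed by 3.38 ± 0.322 (adjusted p = 0.000378), Orm2 by 3.29 (adjusted p = 0.000926) and Fam107a, which encodes an actin-associated protein, by 3.02 (adjusted p = 0.000337). Ccl2 (-3.42 ± 0.683, adjusted p = 0.0432) and Cxcl5 (-2.81, adjusted p = 0.00206) fell in 3134 and did not pass in AtT-20. Arhgef3 (-2.40, adjusted p = 0.00188), Mdm1 (-2.32, adjusted p = 0.000337) and Nqo1 (-2.04, adjusted p = 0.0056) rose more in AtT-20, and their mean responses in 3134 were 0.47, 0.10 and -0.19. Orm1 (4.82 ± 0.662, SD, n = 2) and Ccl2 (4.12 ± 0.156, SD, n = 2) lay at 0 h in AtT-20 below the log2 level of 6.59 that a gene needed to be tested, and so did Pdk4, Lcn2, Orm2, Fam107a and Cxcl5, so a fall of these genes there could not be seen. The difference for Orm1 exceeds its rise of 3.94 in 3134 by a change of -0.90 at that level in AtT-20, which did not pass. Arhgef3 and Nqo1 lay below the level at 0 h in AtT-20 too, which limits the size of their rise, as it does for Ccl3 and Pcdh17.

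The response differed for 80 genes, 60 of them with the higher value in 3134 and 20 with the lower. Of the 80, 57 rose in 3134 alone by the tests within the lines, 3 rose in both and more in 3134, 12 fell in 3134 alone, and 8 passed in AtT-20 and not in 3134. Fkbp5 rose in both lines and by 1.89 ± 0.182 more in 3134 (adjusted p = 0.000378) and Per1 by 1.16 more (adjusted p = 0.0258). The response of Tsc22d3 was higher in 3134 by 1.99 (adjusted p = 0.04). The difference was not resolved for Nr3c1 (-0.37, adjusted p = 0.907) or Pomc (-0.41, adjusted p = 0.999). As a list, the glucocorticoid-induced genes rose more in 3134 (10 and 0 of 32, 19 and 1 with the block, 18 and 1 adjusted over the list alone; median 0.92, adjusted p = 1.4e-22; adjusted p = 0.00919 with an estimated correlation). The cytokine list lay lower (0 and 3 of 15, 0 and 7 with the block, 0 and 6 adjusted over the list alone; median -0.63, adjusted p = 4.57e-06; adjusted p = 0.0102 with an estimated correlation, and adjusted p = 0.133 with the block and an estimated correlation). The matrix list lay lower with adjusted p = 0.0283 (adjusted p = 0.112 with an estimated correlation), and the cell cycle list passed only with the block (adjusted p = 0.0249; adjusted p = 0.687 with that and an estimated correlation), with 0 of 34 members called. At 0 h in AtT-20, 8 of the 15 cytokine genes and 12 of the 20 matrix genes lay below the log2 level of 6.59, where a fall could not be seen, so the lower values of these lists do not show that AtT-20 responded less. Of the 32 induced genes, 7 lay below that level at 0 h in AtT-20, among them Pdk4 and Lcn2, against 3 in 3134. This can limit the size of their rise. With the block the response differed for 298 genes (200 and 98). The count was 23 without 3134 0 h replicate 1, 31 without 3134 0 h replicate 2 and 42 without AtT-20 0 h replicate 2. On the deposited scale with the block, where the median of all genes moved by -0.237, the split was 79 and 89, and the induced genes still lay higher. The shift goes the way of the other 2 lists, so that scale does not test them, but they kept their direction with centred arrays. Without the block that scale gave 3 genes.

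**Figure D3:**
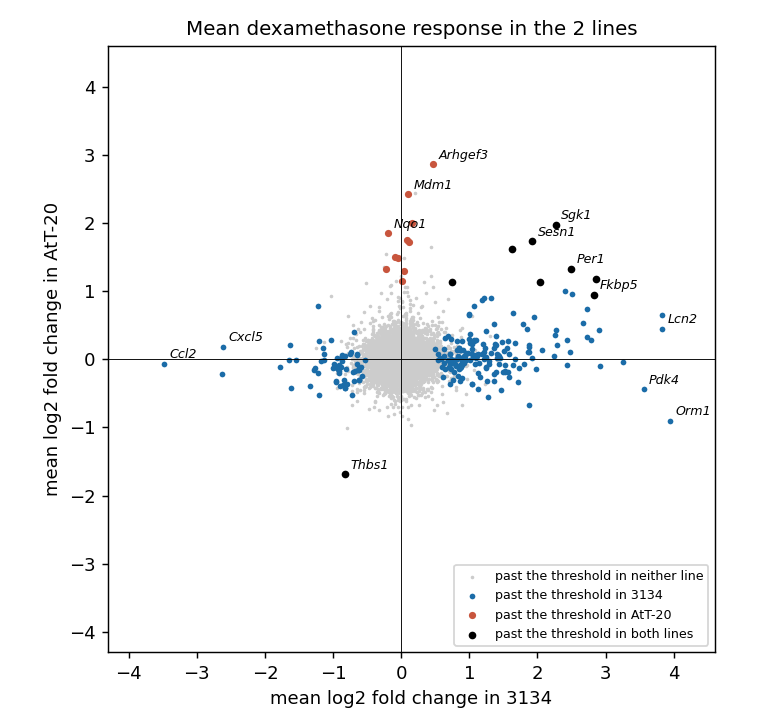
Mean log2 fold change over 2, 4 and 8 h against 0 h in 3134 (horizontal axis) and AtT-20 (vertical axis), with 1 point per tested gene coloured by the line in which it passed the threshold (black for both). Of the genes that passed in 3134, 156 of 241 had the same sign in AtT-20, and 8 genes rose and 1 fell in both.

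Sgk1, Sesn1, Per1, Fkbp5, Ddit4, Arrdc2, Usp2 and Klf15 rose in both lines, and Thbs1 fell in both. Klf15, a transcription factor of amino acid and glucose metabolism, was chosen after its values were seen and rose by 1.62 in both (difference adjusted p = 0.999). Sgk1 rose by 2.27 in 3134 and 1.98 in AtT-20 and Sesn1 by 1.92 and 1.74. Ddit4 rose by 2.03 and 1.14 (difference adjusted p = 0.111; 0.00765 with the block), Arrdc2 by 2.86 and 1.18 (difference adjusted p = 0.00294) and Usp2 by 0.75 and 1.14. Thbs1 was at -0.82 in 3134 and -1.69 in AtT-20 (difference adjusted p = 0.144; 0.0433 with the block). The 8 genes that rose in both compare with 0.341 expected for independent lists of 178 and 19 genes (Fisher's exact test, p = 5.83e-10), and the 1 that fell in both with 0.006 for lists of 63 and 1 (Fisher's exact test, p = 0.00635). The lines had separate controls, and 0 genes went opposite ways. The fit shared 1 spread per gene between the lines, which can favour calls in both, so the expected numbers are approximate. With each line fitted alone, the count in both was 3. At an adjusted p under 0.01, 7 rose in both (0.157 expected, Fisher's exact test, p = 6.78e-11) and 0 fell in both. Of the 241 genes of 3134, 64.7% had the same sign in AtT-20, and the difference passed for 72. Of the 20 genes of AtT-20, 16 had the same sign in 3134 and the difference passed for 11. In the blocked fits 17 rose in both (2.74 expected, Fisher's exact test, p = 9.44e-10), 1 fell in both (0.453 expected, p = 0.368 by Fisher's exact test) and 3 and 4 went opposite ways. Without AtT-20 0 h replicate 2 the count in both was 3.

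Early and late responses were compared in 3134 as 8 h against 2 h. Both groups were treated, so this comparison cannot separate a late effect of the hormone from time in culture. The retinal dehydrogenase gene Aldh1a1 was higher at 8 h by 1.88 ± 0.265 (adjusted p = 0.0244) and the focal adhesion gene Tns1 by 1.86 ± 0.242 (adjusted p = 0.023). Fam107a was higher by 1.59 ± 0.224 (adjusted p = 0.0244) and Otulinl by 1.15 (adjusted p = 0.0365). Slc7a11 was lower by log2 -2.19 ± 0.238 (adjusted p = 0.0109), Dlgap2 by -1.73 ± 0.238 (adjusted p = 0.0244) and Pfkfb3, an enzyme that promotes glycolysis, by -1.39 ± 0.218 (adjusted p = 0.0423). In all, 6 genes were higher and 3 lower. In AtT-20, limma called 0 genes between 4 h and 2 h, with 140 at an unadjusted p under 0.05 and 2 with the run as a block. In 3134 the block gave 198 genes (114 and 84; 28 and 228 on the deposited scale, 169 and 181 with centred arrays). The count of 9 rested on single arrays and was 0 by limma without 8 h replicate 2, 2 h replicate 1 or 2 h replicate 2, where all arrays gave 724 genes at an unadjusted p under 0.05. It was 5 without 8 h replicate 1, 3 without 0 h replicate 1 or 0 h replicate 2, and 5 without AtT-20 4 h replicate 1 or replicate 2.

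Before treatment the lines differed in 5414 of the 9927 genes, 2412 of them higher in 3134 and 3002 lower. The ferroxidase gene Cp (8.70 ± 0.153, adjusted p = 6.55e-12), the secreted phosphoprotein gene Spp1 (8.50), Gsta4 (8.50), Anxa1 (8.49), the fibronectin gene Fn1 (8.44), S100a11 (8.40), S100a10 (8.13) and S100a6 (8.05) had the largest measured differences above AtT-20. The prohormone convertase gene Pcsk1 (-8.79 ± 0.15, adjusted p = 6.55e-12), Pomc (-8.03 ± 0.367, adjusted p = 3.6e-09), the granin Scg3 (-8.03), Resp18 (-7.91), Efcab1 (-7.51), Ddc (-7.48), Atp1b1 (-7.38) and Uchl1 (-7.26) had the largest below. All of these genes lay under the log2 level of 6.59 in the line where they were lower, so the differences are lower bounds of their size and their order is not resolved. Pomc may be limited at the upper end as well, since 4 of its 5 probesets lay above the 99th percentile in AtT-20. Saturation itself was not measured. Nr3c1 was higher in 3134 by 1.504 ± 0.168 (adjusted p = 9.2e-06), at log2 10.43 ± 0.057 (SD, n = 2) against 8.93 ± 0.105 (SD, n = 2). Per1 was lower by log2 -1.23 (adjusted p = 8.48e-05), and Fkbp5 (-0.02, adjusted p = 0.937) and Tsc22d3 (-0.11, adjusted p = 0.809) did not pass.

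All 10 tested corticotroph and pituitary lineage genes were lower in 3134 (median -3.64, adjusted p = 1.89e-06; adjusted p = 0.00968 with an estimated correlation), among them the lineage factors Tbx19 (-7.21) and Neurod1 (-5.73). Of 23 secretory granule genes, 21 were lower and 2 higher (median -4.29, adjusted p = 1.21e-09; adjusted p = 0.00968 with an estimated correlation). Chgb (-7.12), Chga (-6.64) and Snap25 (-6.25) were lower, and Rab3b (2.39) and Stx1a (0.88) higher. Of 16 mesenchymal genes, 11 were higher and 0 lower (median 4.08, adjusted p = 1.77e-07; adjusted p = 0.0169 with an estimated correlation, and adjusted p = 0.0661 with that and the block). Vim (7.95), S100a4 (6.35), Col1a2 (6.24) and Pdgfrb (5.84) were higher and Col1a1 (0.20, adjusted p = 0.599) did not pass. Of 20 matrix genes, 17 were higher and 1 lower (median 2.90, adjusted p = 7.07e-08; adjusted p = 0.00793 with an estimated correlation). Adamts1 (7.01) and Timp1 (6.51) were higher and Serpine2 (-6.32) lower. Of 15 cytokine and NF-kB genes, 12 were higher and 3 lower (median 1.84, adjusted p = 0.000468; adjusted p = 0.0185 with an estimated correlation, and adjusted p = 0.115 with that and the block). Of 20 lipid genes, 10 were higher and 2 lower (11 and 4 with the block; median 0.49, adjusted p = 0.00664; adjusted p = 0.045 with an estimated correlation, and adjusted p = 0.203 with that and the block). Of 8 epithelial genes, 7 were lower and 1 higher (median -3.75, adjusted p = 0.000468; adjusted p = 0.0622 with an estimated correlation). The keratins Krt18 (-5.01) and Krt8 (-4.91) were lower and Krt14 (0.96) higher. Cholesterol genes were higher (12 and 0 of 21, 15 and 1 with the block, 13 and 0 adjusted over the list alone; median 0.83, adjusted p = 0.00598; adjusted p = 0.0622 with an estimated correlation). Transporters were lower (2 and 12 of 16, 4 and 12 with the block, 3 and 12 adjusted over the list alone; median -1.05, adjusted p = 0.011; adjusted p = 0.0557 with an estimated correlation). Both tested immune genes were higher (median 2.20, adjusted p = 0.0444; adjusted p = 0.211 with an estimated correlation, and adjusted p = 0.0788 with the block). The runs of the lines carry different serial numbers, so the comparison at 0 h also sets different runs against each other. Each list member named here with a difference over 5 lay under the log2 level of 6.59 in the lower line, and its difference is a lower bound. The directions of the 10 lists held with centred arrays. On the deposited scale with the run as a block the median of all genes moved by 0.232, so that scale tests only the 4 lists that lay lower, which still did. There 3321 genes were higher and 2045 lower, and without the block 1039 and 921.

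The series measured exons, so unequal change among the probesets of a gene was tested in the mean response. In 3134 cells, 9 of the 12 probesets of Tsc22d3 rose by over 1 on the log2 scale while 3 moved by less than 0.5, over a range from -0.36 to 4.16 (adjusted p = 5.03e-07). Sesn1 ranged from -0.23 to 2.40 over 11 probesets (adjusted p = 1.26e-06) and Arrdc2 from 0.36 to 3.73 over 21 (adjusted p = 2.86e-06). In AtT-20, 1 of the 19 probesets of the stress kinase gene Mapk9 was at 2.76 and the other 18 moved by less than 0.5 (adjusted p = 1.92e-08). Sgk1 ranged from -0.43 to 3.15 over 18 probesets (adjusted p = 1.92e-08) and Arhgef3 from -0.17 to 3.61 over 13 (adjusted p = 6.47e-07).

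Of 11438 genes, 30 passed this test in 3134 and 49 in AtT-20, and 21 and 7 of them also changed as genes. Arrdc2, Klf15, Per1, Sesn1 and Sgk1 passed in both lines. These counts are not evidence of unequal exon change at the nominal error rate. On simulated unchanged arrays in which each probeset kept its own spread, the same test called 313 genes for 3134 and 349 for AtT-20. That simulation took each estimated spread as the true one, which overstates how unequal the spreads are. It called far more genes than the real arrays did, so it gives no error rate for these counts. With an own spread per probeset, which called 0 and 1 genes on such arrays, 2 genes passed in 3134, Prr15l (adjusted p = 0.00864) and Selenbp1 (adjusted p = 0.0292), and 1 in AtT-20, Sgk1 (adjusted p = 0.0341). Prr15l and Selenbp1 were chosen after their values were seen. With the block, the first test called 193 and 258 genes and the own-spread test 9 and 0. Single arrays moved the count of the first test in 3134 to 8 without 0 h replicate 1, 18 without 2 h replicate 2 and 16 without 8 h replicate 2. The count in AtT-20 moved to 1338 without its 0 h replicate 1, 11 without its 0 h replicate 2, 27 without 3134 0 h replicate 1 or replicate 2 and 31 without 3134 2 h replicate 1 or replicate 2.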

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

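The tests of the receptor's level, of whether AtT-20 cells responded and of unequal spread among probesets were chosen only after the result was seen, and the own-spread exon test was added then; the others were fixed before their result was seen.

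What brought these results up is that the dexamethasone response differed between the lines by the test of the difference itself, for 80 genes. The difference of mean responses, 3134 minus AtT-20 on the log2 scale, was 4.845 for Orm1, 4.002 for Pdk4, 3.379 for Lcn2, 3.293 for Orm2, 3.019 for Fam107a, 1.889 for Fkbp5, 1.987 for Tsc22d3 and 1.16 for Per1. It was -3.416 for Ccl2, -2.807 for Cxcl5, -2.399 for Arhgef3, -2.32 for Mdm1 and -2.044 for Nqo1. Groups of 1 or 2 arrays are too small for a test of single arrays against the rest of their group.

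More genes changed in 3134 (241) than in AtT-20 (20). Noisier or fewer AtT-20 arrays would leave the covariance of fold changes between the runs, which holds no array noise, alike in both lines, but over 2 and 4 h it was 6.416 times as large in 3134 (0.0743 against 0.0116, 95% bootstrap interval of the ratio 4.879 to 8.97), which argues against noise or number as the whole cause. Absence of the genes from AtT-20 is argued against as the whole cause too: 165 of the 241 lay above the filter level there, and their median AtT-20 change was 0.098 of the 3134 change (interval 0.052 to 0.126), though 76 (31.5%) lay below it, against 8.8% of all tested genes. A lower level of the receptor's transcript in AtT-20, by log2 1.504 for Nr3c1, stays open as a biological hypothesis that may contribute, since 2 lines cannot separate it from any other difference between them. Other differences between the lines, such as their tissue, were not tested. Both bootstrap intervals given here resampled genes as if they were independent, so they leave out the spread between arrays and runs.

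Probesets of some genes changed unequally by diffSplice, in 30 genes of 3134 and 49 of AtT-20. Of these, 21 and 7 also changed as genes, and 58 of their probesets lagged behind their gene. At the floor or the ceiling lay 20.7% of the 58 (95% binomial interval 11.2% to 33.4%, which takes probesets of 28 genes as independent). This does not decide on dimness. A probeset had to reach the filter level in some group to be tested, so few could lie at the floor. At the ceiling, above the 99th percentile, lay 1 of 43 in 3134 and 0 of 15 in AtT-20. That argues against saturation as the main cause for these genes. Dimness stays open. Among all called probesets, 20 of 42 in 3134 and 54 of 69 in AtT-20 lay below the filter level at 0 h. Dropping such probesets left 16 and 7 genes. Called probesets repeated in both runs for 100% in 3134 and 52.2% in AtT-20. Unchanged simulated arrays gave 81.4% and 78% by selection alone, so the bound of 80% set beforehand was wrong. The simulation did not match the number of real calls, so these shares decide nothing alone. In AtT-20 the called probesets deviated from their gene by 0.715 in the first run and 2.6 in the second (medians). Their 0 h arrays differed by 2.025, against 0.384 for all probesets (0.315 and 0.272 in 3134). The AtT-20 calls therefore rest in large part on a gap between its control arrays. Spread pooled over unequal probesets may contribute to the AtT-20 calls. Called probesets had 2.19 times the pooled spread of their gene there (median, 95% bootstrap interval 1.9 to 2.5, which takes probesets as independent). With an own spread, 1 of the 49 passed. Unchanged simulated arrays gave 349 genes, more than the 49 called, so the simulation overstates the unequal spread and sets no error rate. In 3134 pooled spread stays open, since the ratio of 1.07 (0.87 to 1.2, and 0.84 for all probesets) is not told from 1. There 2 of the 30 passed with an own spread (8 with the block). Simulated arrays gave 313 genes, again more than were called. No biological explanation such as another promoter was tested.

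A fall of Pomc in AtT-20 was not resolved, at 0.08 ± 0.312 over the 3 times with a 95% confidence interval from -0.603 to 0.762. Cells that did not respond are argued against by 5 glucocorticoid-induced genes that rose in them. Saturation could hide a fall: 4 of the 5 Pomc probesets lay above the 99th percentile (log2 12.25), and the 1 below it, at log2 6.61, changed by -0.424. A stable transcript that outlasts 8 h stays open and was not tested.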

How the results depend on the processing

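The deposited scale, centred arrays, the mean of 2 and 4 h, the 0 h probeset filter and the own-spread exon test were chosen only after the result was seen. Counts moved with the processing far more than the directions of the named genes did, most of which were picked as past the threshold. The split of all called genes did turn with the scaling. With the run as a block, 3134 at 8 h had 427 higher and 355 lower quantile normalized, and 125 and 1029 on the deposited scale. Medians of some lists that did not pass also changed sign. The cause was not tested unless stated. Of 178 pairs of a named gene and a comparison, 143 of them past the threshold, 165 kept direction and side of the threshold with the run as a block, while 12 gained the call, 0 lost it and 1 turned. With the mean over probesets 156 kept both, with each line alone 111 (31 lost the call) and on the deposited scale 80 (94 lost it). With 1 array left out, 2407 values kept both, 211 lost the call, 2 gained it and 11 turned. Signal near background limits dim genes, such as Orm1 in AtT-20, and saturation may limit Pomc.

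With the replicate block by run, the counts at 2, 4 and 8 h and over the mean were 296, 513, 782 and 650 in 3134 and 32, 86, 44 and 86 in AtT-20. The difference gave 298, 8 h against 2 h 198, 4 h against 2 h 2, both lines 18 and the exon test 193 and 258. All genes called without the block passed with it, and among the lists at the preset correlation it changed only the calls of the cell cycle list in the difference and of the immune list at 0 h. With the mean over probesets the counts were 201, 314, 404 and 389, then 22, 27, 23 and 34, then 148 for the difference, 76 for 8 h against 2 h and 16 for both lines. Without the filter 3134 at 8 h had 143, AtT-20 at 4 h 10, the difference 47 and 8 h against 2 h 1. With each line alone (fewer arrays) AtT-20 had 1, 4, 2 and 6, 8 h against 2 h 3 and both lines 3. Quantile normalization within lines gave 18 and trend with robust 24 for 8 h against 2 h. On the deposited scale, where run levels enter the spread, 3134 had 12, 9, 12 and 23 and AtT-20 0, 0, 0 and 1 by limma. The difference had 3, 8 h against 2 h 0, the lines at 0 h 1960 and both lines 0. With that scale and the replicate block 3134 had 466 at 4 h, 1154 at 8 h and 537 over the mean, AtT-20 28, 31, 37 and 48, the difference 168, 8 h against 2 h 256 and 4 h against 2 h 1. Centred arrays gave 8 for AtT-20 at 4 h and 2 for 8 h against 2 h; with the replicate block they gave 315, 555, 937 and 671, then 38, 75, 37 and 76, then 309, 350 and 2, with 21 for both lines. An estimated correlation left 3 lists in 3134 and 1 in AtT-20. The exon test gave 16 and 7 with the 0 h filter, 2 and 1 with own spread, and 9 and 0 with own spread and the block. With 2 and 4 h only, the mean response gave 206 and 18 genes and the difference 64. The other alternatives kept each count within 1.5 times, and no value for AtT-20 at 8 h could be had without its only array.

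Leaving out 1 array at a time, with a lone array assumed to vary like the other groups, gave 38 to 125, 71 to 206, 75 to 217 and 93 to 244 genes in 3134 and 3 to 9, 7 to 19, 7 to 11 and 6 to 25 in AtT-20. It gave 23 to 83 for the difference, 0 to 11 for 8 h against 2 h, 0 to 0 for 4 h against 2 h, 4419 to 5504 at 0 h, 3 to 10 in both lines, 6 to 8 and 2 to 5 lists, and 8 to 38 and 11 to 1338 genes in the exon test. Over the alternatives the list adjusted p ran from 5.72e-48 to 0.000824 for induced genes, 7.43e-12 to 0.00349 for cytokines, 7.42e-07 to 0.00528 for matrix, 1.38e-06 to 0.203 for immediate early, 0.00021 to 0.203 for clock, 0.000846 to 0.247 for cell cycle and 0.0209 to 0.203 for cholesterol genes in 3134. In AtT-20 it ran from 3.31e-25 to 0.016 for induced and 5.73e-06 to 0.229 for clock genes.

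The values that turned were of genes that passed in neither setting. With the mean over probesets Pomc was 0.047, 0.08, 0.266 and 0.131 at 2, 4 and 8 h and over the mean in 3134, -0.26 at 2 h, -0.052 at 4 h and -0.054 over the mean in AtT-20, and its difference was 0.185. With centred arrays it was 0.076 in 3134 at 8 h with or without the block, and in AtT-20 -0.05 at 4 h with or without it, -0.139 at 8 h (-0.239 with it) and -0.034 over the mean (-0.067 with it). In AtT-20 on the deposited scale it was -0.209 at 4 h with or without the block and, with it, -0.068 at 8 h and -0.063 over the mean. At 8 h in AtT-20 it was -0.065 with the block and -0.039 normalized within lines, and Nr3c1 was 0.298 on the deposited scale (0.057 with the block). Leaving out arrays, Pomc ran from -0.938 to 0.131 at 4 h and -0.576 to 0.229 at 8 h in 3134, and in AtT-20 from -0.165 to 0.329, -0.209 to 0.285, -0.128 to 0.366 and -0.168 to 0.327 at 2, 4 and 8 h and over the mean. At 0 h Fkbp5 was 0.375 on the deposited scale and 0.114 with centred arrays, with or without the block, 0.014 without 3134 0 h replicate 2 and from -0.103 to 0.069 (without AtT-20 0 h replicate 1) leaving out arrays. Tsc22d3 was 0.135 on the deposited scale with or without the block and from -0.233 to 0.017 (without AtT-20 0 h replicate 1) leaving out arrays.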

Other observations

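All tests in this part were chosen only after the result was seen, from lists written once leading genes had been noticed.

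Genes of ribosome biogenesis lay lower late in the 3134 response. Leaving out Gnl3, Gar1 and Rpp40, which had been seen first, 43 genes were tested, and 39 of them lay lower at 8 h than at 2 h, with a median of -0.36 (-0.27 and -0.41 in the separate runs; p = 0.0061 by limma's camera with an estimated correlation, 0.0137 with the run as a block). By limma 0 of the 43 passed singly, and 7 with the block. Against 0 h the list lay lower at 8 h (p = 0.0078 by limma's camera with an estimated correlation; 4 genes passed singly, and 17 with the block), where Polr1b (-0.91), Nop56 (-0.87), Nhp2 (-0.86) and Utp15 (-0.83) fell. By limma's camera with an estimated correlation it was not resolved at 2 h (p = 0.465), over the mean of 3134 (p = 0.0726; 0.087 with the block) or over the mean of AtT-20 (p = 0.851). Lists with most members below the filter level in 3134 lay higher at 8 h than at 2 h (medians 0.236 epithelial, 0.097 corticotroph, 0.085 secretory granule). Lists of mostly expressed genes went both ways, among them transporters (-0.222), heat shock genes (-0.108), clock genes (0.14) and feedback regulators (0.175). A shift between dim and bright genes was not tested as a cause. A late fall of ribosome production in 3134 cells is a hypothesis that the ribosome values leave open, and its list was written from the same data. Whether such a fall would follow the hormone or time in culture cannot be told from these arrays.

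Acute phase genes other than those seen first (Lcn2, Orm1, Orm2, Lbp and Hp) were 5 in number after the filter, and 2 of them rose over the mean of 3134, F3 (1.44, adjusted p = 0.0106) and Serpina3n (0.99, adjusted p = 0.0363). The 5 had p = 0.0308 by camera with an estimated correlation and 0.071 with the run as a block. Of those seen first, Lbp rose by 2.67 ± 0.311 and Hp was at 0.85 (adjusted p = 0.47; 0.00464 with the block).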
